A study of Rattus norvegicus with 9 samples.

How the data were processed

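The series holds 9 RNA-seq libraries of rat pXEN cells, 3 each from the media T, LPE and CPE, and groups and replicate numbers were taken from the sample labels. Per the labels' protocols, ribosomal RNA was removed from total RNA, a directional (strand-keeping) kit was used to make cDNA from random primers with PCR enrichment, and fragments were read in pairs of 101 cycles. The labels name both HiSeq2500 and HiSeq2000 as the sequencer. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Trimmomatic 0.33, STAR 2.5.1 and DESeq2 (version not given in the sources used here), with build rn6. The gene annotation is not given in the sources used here.

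Each deposited table holds raw counts of reads per gene from the authors, without a header, in 4 columns: the gene symbol, the reads on either strand, the reads on the strand of the first read, and the reads on the opposite strand. Column 4 was used as the gene-strand count because the kit is directional and it holds nearly all gene reads, the other strand having 0.822% to 0.986% of the reads of both. The deposited tables also count, in 4 summary lines, unmapped reads (6.32% to 8.67%), reads mapping to several places (64.9% to 67.6% in T and 51.7% to 59.9% in LPE and CPE), reads outside genes (13.9% to 26.1%) and ambiguous reads (1.11% to 2.46%). These were kept out of library sizes and tests. Reads mapping to several places enter no gene, so genes with near-identical copies are under-counted, and such genes are uncertain. The tables list 17315 genes, of which 5395 had 0 counts in all 9 libraries. Symbols were used as the tables give them, and 14810 matched a symbol and 2114 only a synonym in the RefSeq table of GRCr8, a different build, from which no coordinates were used. No genome sequence or gene length was used here, so positions, length and GC content are not analysed.

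Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test on all 9 libraries with a mean per medium, TMM factors and filterByExpr (at least 10 counts in enough libraries and 15 in total), which kept 9130 genes. Each p was adjusted by Benjamini-Hochberg over the 9130 genes of a comparison, and a gene is called at an adjusted p under 0.05. Adjusted p-values printed for genes are edgeR's. CPM are counts per 1e6 counts with TMM factors, given as mean ± SD of 3 libraries, and log2 fold changes come from the fit. Where a group had 0 counts in all its libraries, the fold is a lower bound against 3 counts per library, and this covers counting error only. At the depths given in the results, 1 count is worth 0.226 to 0.589 CPM. Principal components and correlations used log2 CPM with a prior or pseudocount of 2. The LPE and CPE libraries vary more between replicates than T, and edgeR shares its estimate of the spread between groups.

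Before the data were examined, 26 gene lists with 513 genes (471 in the tables) were fixed from the cell type, the additives and cell types that could be present: primitive and extraembryonic endoderm regulators, visceral endoderm markers, parietal endoderm markers, basement membrane genes, epithelial junction and keratin genes, mesenchymal genes, Wnt/beta-catenin targets, Lif/Stat3 targets, glucocorticoid receptor targets, serum response factor and Yap targets, Mapk/Erk output genes, Bmp targets, Tgf-beta and Nodal targets, cholesterol synthesis genes, fatty acid synthesis genes, retinoic acid targets, cell cycle genes, glycolysis and hypoxia genes, interferon-stimulated genes, amino acid and unfolded protein response genes, lysosome genes, neural markers, endothelial and blood markers, pluripotency and epiblast markers, trophoblast markers and fibroblast markers. The 23 lists with at least 5 tested members were tested with camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the 23 lists of a comparison, and again with the correlation estimated and with fry. Camera compares the members of a list with all other genes tested, whereas fry asks whether they move one way and compares them with nothing. The median, the mean and camera's direction differed in sign in 21 of the 69 list results, of which 0 were called. Genes were named by a rule fixed then too: the 8 largest rises and the 8 largest falls of each comparison among called genes with at least 5 CPM in the higher group, no overlap of the 3 against 3 libraries and a gene symbol that is not a placeholder, up to 2 members of a described list with the largest rise and up to 2 with the largest fall (at least 1 CPM), and 15 marker genes. Members named outside this rule are stated to be so where they appear. Values of some genes that the rule picks are not reported here.

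The method was tested on simulated counts with 200 genes changed by 2-fold or 4-fold in means and library sizes of the real libraries. For LPE against T (9240 genes) it found 37% of 2-fold and 79% of 4-fold changes with 5 false calls among 121, for CPE against T (9137 genes) 40% and 73% with 1 among 114, and for CPE against LPE (9244 genes) 45% and 77% with 6 among 128. Among the genes left unchanged in these simulations, 3.75%, 1.99% and 7.83% had an edgeR p under 0.05. The share for CPE against LPE is above that level, so p-values there may run too small. Changes of 2-fold were therefore often missed in these simulations, whose changed genes were drawn from those with a mean of at least 5 CPM. The real comparisons called many more genes, which loosens the adjusted threshold, so these shares need not hold for them. Alternatives fixed in advance were DESeq2 1.42.0, other normalizations and filters, fits of only the 6 libraries compared, a block for the replicate number, stricter thresholds, leaving out the 20 most abundant genes and leaving out each library. Others were added after the data were seen: counts of either strand, only genes of at least 20 CPM, limma voom with weights per group, counts divided by the replicate noise of their group, and list tests in the 6 libraries compared. Figures were drawn with matplotlib 3.10.9.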

Results

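Gene expression was measured by RNA sequencing in rat pXEN cells, which are primitive extraembryonic endoderm stem cells, the cultured counterpart of the early lineage that forms the yolk sac endoderm. All libraries came from the line RX1 of the WKY strain, and 9 libraries fell into 3 groups of 3 by culture medium. The T cultures were grown on fibronectin in a traditional medium with 2% fetal bovine serum, 0.5 µM dexamethasone (a synthetic glucocorticoid) and 10 ng/ml each of Lif, Pdgf and Egf. The LPE cultures were grown without serum or dexamethasone on collagen, with 10 ng/ml each of Lif, Pdgf and Egf. The CPE cultures differed from LPE, as far as the labels say, in having 1 µM Chir99021, a Gsk3 inhibitor that activates Wnt signalling, in place of Lif. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The question posed by the series is how defined media shape the state and form of these cells.

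Reads assigned to genes ranged from 1698764 to 2161228 per library in T, from 3119049 to 3233526 in LPE and from 3127352 to 4418465 in CPE, which was 7.96% to 14.8% of all reads. Although they had fewer reads, the T libraries detected more genes, 10143 to 10621 with at least 1 count, against 8607 to 9314 in LPE and 9162 to 9878 in CPE. After thinning every library to 1698764 reads the counts of genes were 10143 to 10465, 8581 to 9251 and 9145 to 9751. Genes with exactly 1 count numbered 511 to 791 per library in T and 26 to 92 in LPE and CPE. Between replicates, genes of 20 to 99 counts, summed over the pair of libraries, differed by 1.35 to 2.05 times the sampling variance in T, by 9.93 to 15.6 times in LPE and by 7.38 to 11.7 times in CPE. No pair of libraries differed by less than the sampling noise, so all 9 were kept as separate samples. The lowest value over genes of at least 20 counts, summed over the pair, was 1.94 in T. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.990 to 0.994 within T, 0.959 to 0.973 within LPE and 0.971 to 0.982 within CPE.

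**Figure D1:**
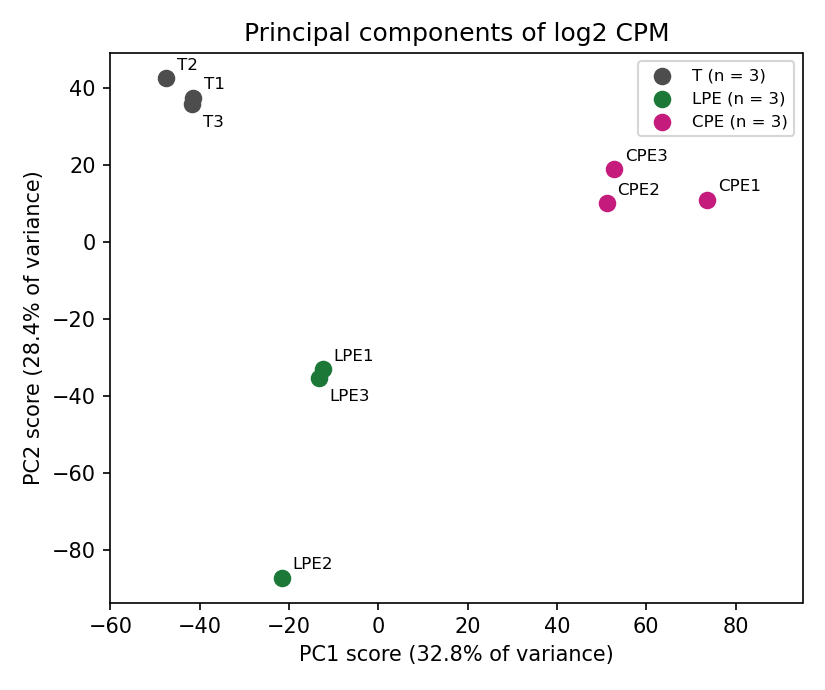
Scores of the 9 libraries on the first principal components of log2 CPM, with the share of variance on each axis; each point is a library and the colour its medium. The CPE libraries lie apart from the others on PC1 (32.8% of variance), T and LPE part on PC2 (28.4%), and LPE replicate 2 lies apart from the other LPE libraries at -87.1 on PC2.

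**Figure D2:**
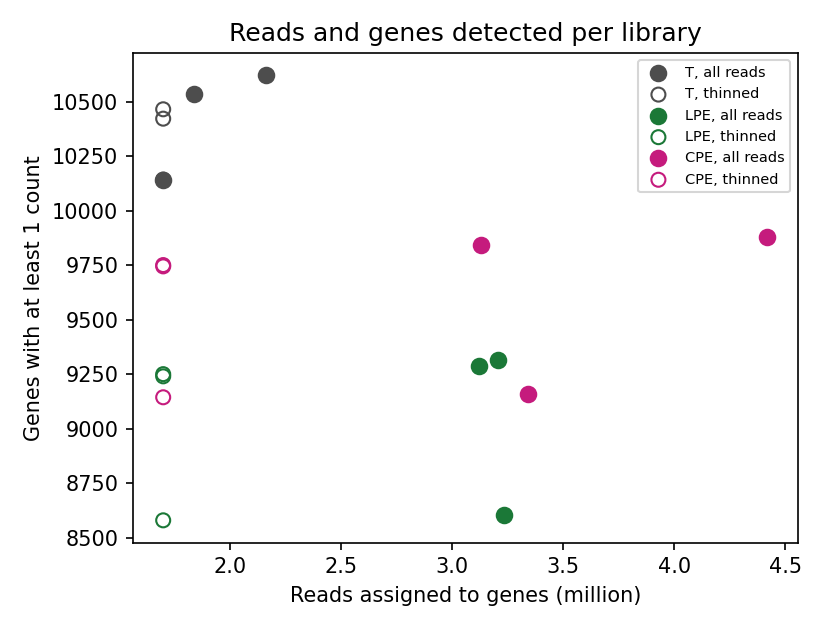
Genes with at least 1 count against reads assigned to genes (in units of 1e6 reads) for each library; filled points use all reads and open points the counts after thinning to 1698764 reads. The T libraries detect 10143 to 10621 genes from fewer reads than the LPE and CPE libraries, which detect 8607 to 9878.

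Regulators of the endoderm lineage were expressed in all 3 media. Gata4, a transcription factor of the primitive endoderm, stood at 903 ± 80.3 CPM in T, 836 ± 42.2 in LPE and 927 ± 31.3 in CPE (mean ± SD, n = 3 each), and no comparison called it. Gata6, its relative, was 1.83-fold higher in LPE and 1.47-fold higher in CPE than in T. The growth factor receptor gene Pdgfra was 1.599-fold lower in LPE and 1.79-fold lower in CPE than its 464 ± 24.1 CPM in T. Sox17 was 1.803-fold lower in CPE than in T and 1.49-fold lower than in LPE, while LPE and T did not differ by the test (984 ± 81.1 and 1190.1 ± 168 CPM). Pou5f1, which encodes the pluripotency factor Oct4, had 253 ± 28.6 CPM in T, 264 ± 54.9 in LPE and 132 ± 32.1 in CPE, and was 1.998-fold lower in CPE than in LPE. Thbd, a marker of parietal endoderm, was not called in any comparison, with 580.2 ± 6.58, 613 ± 94.6 and 482 ± 48.8 CPM. Afp and Lef1 had 0 counts in all 9 libraries and were not tested.

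LPE was compared with T to ask what changed when serum and dexamethasone were left out and the basal medium and coating were replaced, with Lif, Pdgf and Egf kept. Cdh1, Fasn and Nid2 were among the genes higher in LPE than in T. Cdh1, which encodes E-cadherin, rose from 17.2 ± 9.298 CPM in T to 312 ± 52.9 CPM in LPE (n = 3 each), a log2 fold change of 4.16 (SE 0.34, edgeR adjusted p = 3.7e-07). Fasn, the fatty acid synthase gene, rose 7.73-fold to 3650.2 ± 303 CPM, and Nid2, a basement membrane linker, rose 7.38-fold to 277 ± 46.2 CPM. In contrast, Id1 and Id3, which are targets of Bmp signalling, fell 13.1-fold and 38.99-fold. Id3 stood at 2.88 ± 4.44 CPM in LPE, an SD above its mean, so the size of its fold is uncertain. The fibronectin gene Fn1 went from 28.1 ± 6.34 CPM in T to 0 counts in all 3 LPE libraries. In all, 2716 of the 9130 genes tested were called at an adjusted p under 0.05, 1373 higher and 1343 lower in LPE, of which 1366 changed at least 2-fold (768 higher and 598 lower).

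Both lipid synthesis lists were called upward. Of 25 tested cholesterol synthesis genes 15 rose, 0 fell and 10 did not pass the test (16 called when adjusted over the list alone), and the list was called by camera at an adjusted p of 9.2e-10. Fdft1, which encodes squalene synthase, rose 3.53-fold to 254 ± 54.8 CPM. Hmgcs1, an early enzyme of the pathway, rose 2.25-fold to 313 ± 6.17 CPM. Of 14 fatty acid synthesis genes 10 rose, 0 fell and 4 did not pass the test (11 called when adjusted over the list alone), with camera's adjusted p at 8.9e-13, led by Fasn and by the desaturase gene Scd1 (3.497-fold, to 903 ± 135 CPM). Both lists also passed with an estimated correlation between genes (adjusted p = 0.031 for each).

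The junction and matrix lists were also called upward, but not with an estimated correlation. Among 23 epithelial junction and keratin genes 12 rose, 3 fell and 8 did not pass the test (15 called when adjusted over the list alone), and camera called the list upward (adjusted p = 0.0034, but 0.075 as the adjusted p with an estimated correlation). The 3 that fell were all keratin genes, Krt8 (4.88-fold, from 263 ± 38.8 to 53.9 ± 21.9 CPM), Krt18 (2.35-fold) and Krt19, the last of these named after its values were seen (1.698-fold). Of 12 basement membrane genes 8 rose, 1 fell and 3 did not pass the test (9 called when adjusted over the list alone) (adjusted p = 6.5e-09, and 0.11 as the adjusted p with an estimated correlation), among them Nid2. The member that fell was Col18a1, whose call was lost without T replicate 2 or 3 or LPE replicate 1 or 3 (adjusted p = 0.0597, 0.0609, 0.0575 and 0.0587). Of 18 parietal endoderm markers 7 rose, 3 fell and 8 did not pass the test (10 called when adjusted over the list alone) (adjusted p = 0.0021, and 0.2 as the adjusted p with an estimated correlation). They included the proteoglycan gene Srgn (5.16-fold higher, to 1004 ± 54.5 CPM), Lamc1 (3.64-fold higher) and Sparc (1.56-fold higher, to 4106 ± 218 CPM), while Plat fell from 11.9 ± 0.272 to 0.725 ± 1.26 CPM and Pth1r fell 1.76-fold. The parietal and basement membrane lists share members, so they are not separate evidence.

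The other lists were not called in LPE against T, although single members changed. Counts for these lists are given as those that rose and those that fell of the members tested, with the number called when adjusted over the list alone in parentheses. Endoderm regulators moved both ways, 6 and 3 of 17 (10), with Fgfr4 2.71-fold higher and Amn, part of the cubilin receptor, 2.12-fold lower. Counts were 4 and 4 of 10 (8) for visceral endoderm markers and 1 and 1 of 8 (2) for mesenchymal genes, in which Vim rose 2.07-fold to 501 ± 48.5 CPM and Fn1 fell. Summed over Col1a1, Col1a2, Col3a1, Dcn and Lum, fibroblast transcripts reached 1.39 to 31.3 CPM in the T libraries and 0 in LPE and CPE. For signalling outputs the counts were 5 and 1 of 19 (6) for Lif/Stat3 targets, with Tfcp2l1 8.02-fold higher, 0 and 3 of 10 (3) for Bmp targets, 6 and 2 of 20 (9) for serum response factor and Yap targets, 1 and 0 of 16 (0) for Mapk/Erk output, 1 and 1 of 6 (2) for Tgf-beta and Nodal targets and 0 and 0 of 10 (0) for Wnt/beta-catenin targets. Among glucocorticoid receptor targets, 2 and 0 of 14 (2) changed, and Fkbp5, a classical target, had 71.4 ± 11.9 CPM in T with dexamethasone and 78.3 ± 6.29 CPM in LPE without it, which was not called.

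Retinoic acid targets gave 1 and 3 of 6 (4), the retinoic acid-degrading enzyme gene Cyp26a1 falling from 71.7 ± 15.3 to 2.69 ± 4.67 CPM. Cell cycle genes gave 7 and 4 of 26 (12), with Top2a and Rrm2 3.65-fold and 3.08-fold higher and Mcm2 1.57-fold lower. Glycolysis and hypoxia genes gave 6 and 4 of 19 (10), Aldoa rising 3.86-fold and Pkm falling 2.43-fold. Lysosome genes gave 3 and 6 of 19 (10), with the protease gene Ctsb 11.98-fold higher and Ctsd 2.001-fold lower. The remaining counts were 6 and 4 of 19 (10) for amino acid and unfolded protein response genes, 1 and 0 of 7 (3) for interferon-stimulated genes, 1 and 1 of 5 (2) for neural markers and 2 and 0 of 6 (2) for endothelial and blood markers. Adjusted p-values by camera over these 18 lists ran from 0.083 to 0.92.

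By the fixed rule the largest rises in LPE included Zrsr1, which was at least 6.36-fold higher, Ubash3a (at least 6.01-fold), the T-cell leukaemia oncogene Tcl1a (0.3100 ± 0.537 to 25.5 ± 7.18 CPM), the tetraspanin Tspan1, the channel subunit genes Kcnd3 and Cacnb2, and the 5S ribosomal RNA gene Rn5s (32.00-fold, from 5.98 ± 6.82 to 192 ± 39.5 CPM), while the call of Samd11 was lost without T replicate 3 (adjusted p = 0.0507). The largest falls included Kif26a (at least 34.7-fold lower), Fn1 (at least 29.6-fold), Bin1 (at least 26.1-fold), Pon2 (at least 23.7-fold), the transporter gene Slc47a1 (at least 14.1-fold), Zfp286a (at least 13.7-fold) and Mxd4 (at least 12.6-fold), each with 0 counts in every LPE library. Such lower bounds set the empty group at 3 counts per library and cover counting error only, since sequenced reads are not independent molecules. Genes whose 3 LPE libraries all lay above or all below the 3 T libraries made up 47.3% of those tested, against 10% by chance. The LPE libraries had fewer genes detected and more noise between replicates than T (above), so a gene of low count at 0 in LPE may have been missed. Reads that map to several places were not counted, which leaves Zrsr1, Rn5s, Krt8, Krt18 and Actb, all of which have close copies, uncertain. Ribosomal RNA was also removed before sequencing, so Rn5s is uncertain on that account too.

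CPE was compared with T to ask what changed when Chir99021 replaced Lif, serum and dexamethasone were left out and the basal medium and coating were replaced, all at once. The keratin genes Krt8 and Krt18 and the junction genes Cdh1 and Cldn4 were higher in CPE than in T. Cdh1 rose to 348 ± 135 CPM, a log2 fold change of 4.32 (SE 0.34, edgeR adjusted p = 2.4e-07), Krt8 rose 4.27-fold to 1122 ± 198 CPM, and the claudin gene Cldn4 went from 0.883 ± 1.15 to 102 ± 25.6 CPM. Vim, the intermediate filament gene of mesenchymal cells, fell 4.59-fold to 52.7 ± 11.6 CPM. Axin2 and Lgr5, both induced by Wnt signalling, had 0 counts in every T and LPE library and 20.4 ± 16.6 and 35.9 ± 23.5 CPM in CPE. Of 9130 genes, 2928 were called, 1532 higher and 1396 lower in CPE, and 1569 of them changed at least 2-fold (941 higher and 628 lower).

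Of 23 epithelial junction and keratin genes 16 rose, 0 fell and 7 did not pass the test (16 called when adjusted over the list alone), and camera called the list at an adjusted p of 6.2e-11 (0.0061 as the adjusted p with an estimated correlation). Of 25 cholesterol synthesis genes 16 rose, 1 fell and 8 did not pass the test (18 called when adjusted over the list alone) (adjusted p = 3.4e-08, and 0.037 as the adjusted p with an estimated correlation), and the member that fell was Fdps (1.33-fold). Hmgcs1 rose 1.72-fold. Of 14 fatty acid synthesis genes 9 rose, 0 fell and 5 did not pass the test (10 called when adjusted over the list alone) (adjusted p = 5.7e-11, and 0.037 as the adjusted p with an estimated correlation), with Fasn 6.12-fold and the elongase gene Elovl5 4.52-fold higher. Of the 5 neural markers tested 1 rose, 2 fell and 2 did not pass the test (4 called when adjusted over the list alone), and the list was called downward (adjusted p = 0.01, and 0.11 as the adjusted p with an estimated correlation). Stmn2, a tubulin-binding protein gene, fell from 394 ± 11.6 to 18.9 ± 6.56 CPM, Tubb3 fell 4.14-fold, a call lost without CPE replicate 2 (adjusted p = 0.0512), and Dcx rose 14.7-fold.

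The remaining lists were not called in CPE against T. Among endoderm regulators the counts were 9 and 6 of 17 (15), the nuclear receptor gene Hnf4a rising 2.96-fold and Amn and Dab2, both of the endocytic apparatus of the visceral endoderm, falling 13.2-fold and 2.498-fold. Visceral endoderm markers gave 4 and 2 of 10 (6), with Cubn 1.699-fold lower. Parietal endoderm markers gave 5 and 5 of 18 (12), with Srgn 2.62-fold and Lamc1 2.45-fold higher, and Sparc, at 3026 ± 315 CPM, was not called. Basement membrane genes gave 6 and 2 of 12 (10), with Lamb3 lower at 0.606 ± 1.05 against 11.2 ± 3.53 CPM, and mesenchymal genes 0 and 1 of 8 (1). The fibroblast transcripts summed above were at 0 CPM in CPE, as in LPE.

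Wnt/beta-catenin targets gave 4 and 1 of 10 (5), with Lgr5 at least 22.6-fold and Axin2 at least 12.8-fold higher and Myc 2.51-fold lower. These bounds use the CPE means, and Axin2 ran from 7.08 to 39.0 CPM over the CPE libraries. Lif/Stat3 targets gave 3 and 4 of 19 (7), Socs3, the feedback inhibitor of that pathway, falling from 74.5 ± 4.26 to 6.06 ± 1.36 CPM. Bmp targets gave 2 and 4 of 10 (6), Bmp4 rising to 48.4 ± 14.7 CPM and Id1 falling 6.82-fold. Mapk/Erk output genes gave 0 and 4 of 16 (4), with Dusp4 9.07-fold lower, at 3.16 ± 3.65 against 28.7 ± 3.30 CPM. Serum response factor and Yap targets gave 5 and 4 of 20 (9), with Crim1 2.64-fold higher and the tissue factor gene F3 7.15-fold lower. Glucocorticoid receptor targets gave 2 and 2 of 14 (4), with Fkbp5 2.01-fold and Glul 3.63-fold lower and Fgd4 4.31-fold higher. Lysosome genes gave 5 and 2 of 19 (8), in which Grn rose 24.3-fold and Ctsl fell 3.49-fold, and glycolysis and hypoxia genes 5 and 7 of 19 (13), in which Ndrg1 rose to 70.4 ± 20.6 CPM. Cell cycle genes gave 6 and 7 of 26 (15), with Top2a 3.24-fold higher and Bub1 1.94-fold lower.

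Counts were 4 and 4 of 19 (8) for amino acid and unfolded protein response genes, 1 and 0 of 6 (1) for retinoic acid targets, 0 and 1 of 6 (1) for Tgf-beta and Nodal targets, 1 and 2 of 7 (3) for interferon-stimulated genes and 0 and 1 of 6 (3) for endothelial and blood markers. Camera's adjusted p over the 19 lists not called ran from 0.11 to 0.87. Among the largest rises by the fixed rule were the gastric protease gene Pgc (at least 47.3-fold higher), Stac2 (at least 42.1-fold), Nrp1 (at least 37.98-fold), Smpx (at least 29.9-fold) and Syt9 (at least 6.92-fold), all with 0 counts in T. The largest falls were those of Ppp1r16b (at least 16.7-fold lower), the noradrenaline transporter gene Slc6a2 (at least 15.5-fold), Jph1 (at least 13.5-fold), Tmem119 (at least 11.8-fold), Pga5 (at least 11.7-fold), Cnn1 (at least 11.4-fold), Pdlim4 (at least 10.6-fold) and Lmo2 (at least 10.4-fold), with 0 counts in every CPE library. Groups did not overlap for 54.4% of genes, against 10% by chance. The gap in genes detected and in noise between T and CPE (above) is a limit here too. The bounds for genes at 0 counts in CPE again cover counting error only, and the true folds may be lower.

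CPE and LPE differ in the labels by Chir99021 against Lif alone, so this comparison asked what those additives changed on the same coating and in the same serum-free medium. Krt8, Krt18 and Cldn4 were higher with Chir99021, and Vim, Lamc1 and Socs3 were higher with Lif. Krt8 was 20.8-fold higher in CPE, with 1122 ± 198 CPM against 53.9 ± 21.9 in LPE (n = 3 each), a log2 fold change of 4.38 (SE 0.23, edgeR adjusted p = 7.2e-09), and Krt18 was 8.95-fold higher. Vim was 9.498-fold lower, at 52.7 ± 11.6 against 501 ± 48.5 CPM (adjusted p = 7.2e-09). Cdh1 was not called between them (348 ± 135 and 312 ± 52.9 CPM). The test called 1624 genes, 873 higher and 751 lower in CPE, with 806 changed at least 2-fold (458 higher and 348 lower). A fit of only the 6 LPE and CPE libraries, without the less variable T libraries, called 1103 genes.

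For the targets of the exchanged additives, of 10 Wnt/beta-catenin targets 5 rose, 1 fell and 4 did not pass the test (7 called when adjusted over the list alone). By the CPE means, Lgr5 was at least 37.8-fold and Axin2 at least 21.5-fold higher in CPE, and the member that fell was Myc, 4.35-fold lower at 12.05 ± 1.98 CPM. The list was called upward (adjusted p = 0.04, and 0.16 as the adjusted p with an estimated correlation), and the call was lost without LPE replicate 1, CPE replicate 1 or CPE replicate 3 (adjusted p = 0.0557, 0.0552 and 0.087). Of 19 Lif/Stat3 targets 0 rose, 8 fell and 11 did not pass the test (9 called when adjusted over the list alone) (adjusted p = 2.0e-04, and 0.077 as the adjusted p with an estimated correlation). Socs3 was 7.13-fold lower, at 6.06 ± 1.36 against 43.7 ± 29.6 CPM, and Tfcp2l1, a naive pluripotency factor gene, was 4.73-fold lower. Of 16 Mapk/Erk output genes 0 rose, 5 fell and 11 did not pass the test (7 called when adjusted over the list alone) (adjusted p = 0.0011, and 0.062 as the adjusted p with an estimated correlation), among them the phosphatase gene Dusp4 (8.02-fold lower, at 3.16 ± 3.65 against 25.3 ± 1.83 CPM). Of 20 serum response factor and Yap targets 2 rose, 4 fell and 14 did not pass the test (9 called when adjusted over the list alone), with F3 2.96-fold lower and Actb 1.47-fold higher. That list's downward call (adjusted p = 0.048, and 0.31 as the adjusted p with an estimated correlation) was lost without LPE replicate 1 or CPE replicate 2 (adjusted p = 0.0719 and 0.141).

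Of 23 epithelial junction and keratin genes 9 rose, 1 fell and 13 did not pass the test (11 called when adjusted over the list alone), and the list was called upward (adjusted p = 4.0e-05, and 0.054 as the adjusted p with an estimated correlation), with Cldn4 at 102 ± 25.6 against 1.92 ± 3.32 CPM. The member that fell was Lsr, a call lost without LPE replicate 3 or CPE replicate 1 (adjusted p = 0.0677 and 0.0613). Of 18 parietal endoderm markers 1 rose, 9 fell and 8 did not pass the test (13 called when adjusted over the list alone), called downward (adjusted p = 2.7e-05, and 0.077 as the adjusted p with an estimated correlation), the exception being Plat (16.3 ± 5.62 against 0.725 ± 1.26 CPM), and Sparc was 1.36-fold lower. Of 12 basement membrane genes 1 rose, 7 fell and 4 did not pass the test (8 called when adjusted over the list alone), also downward (adjusted p = 2.7e-05, and 0.15 as the adjusted p with an estimated correlation). Lama4 was at least 15.8-fold lower in CPE, Lamb3 was lower at 0.606 ± 1.05 against 22.9 ± 11.3 CPM, Lamc1 was 1.48-fold lower, and Col18a1, the member that rose, was 32.9-fold higher. The reads of Col18a1 in LPE (1.04 ± 1.79 CPM) lay in a single library, so the size of that fold is uncertain.

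Of 19 lysosome genes 7 rose, 2 fell and 10 did not pass the test (10 called when adjusted over the list alone), with Ctsd 4.92-fold higher and Ctsl 2.87-fold and Ctsz 1.55-fold lower. The upward call (adjusted p = 0.0034, and 0.38 as the adjusted p with an estimated correlation) was lost without CPE replicate 1 (adjusted p = 0.108). Of 26 cell cycle genes 1 rose, 6 fell and 19 did not pass the test (8 called when adjusted over the list alone), called downward (adjusted p = 0.0032, and 0.11 as the adjusted p with an estimated correlation), with Rrm2, which makes deoxynucleotides, 3.74-fold and Mcm5 1.49-fold lower. Of 5 neural markers 1 rose, 2 fell and 2 did not pass the test (3 called when adjusted over the list alone), called downward (adjusted p = 5.1e-04, and 0.062 as the adjusted p with an estimated correlation), with Stmn2 12.7-fold and Tubb3 13.7-fold lower and Dcx higher, the latter not called without CPE replicate 1 (adjusted p = 0.0675). Tubb3 stood at 4.70 ± 4.90 CPM in CPE, so the size of its fold is uncertain. Of 6 endothelial and blood markers 0 rose, 3 fell and 3 did not pass the test (3 called when adjusted over the list alone), among them Pecam1 (3.75-fold lower). That downward call (adjusted p = 0.0499, and 0.16 as the adjusted p with an estimated correlation) was lost without LPE replicate 1, LPE replicate 2 or CPE replicate 2 (adjusted p = 0.0557, 0.068 and 0.069). None of the 11 list calls in this comparison held at an adjusted p under 0.05 with camera's estimated correlation, where 7 of 23 lists had an unadjusted p under 0.05, and the rotation test fry called 15.

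Lists that were not called in CPE against LPE included both lipid lists, 2 and 3 of 25 (5) for cholesterol synthesis and 1 and 1 of 14 (2) for fatty acid synthesis, in which Acsl3 was 1.93-fold lower. Hmgcs1 was 1.31-fold lower (adjusted p = 0.038), a call lost on leaving out any library but CPE replicate 3 (adjusted p = 0.0504 to 0.111). Endoderm regulators gave 2 and 5 of 17 (8) and visceral endoderm markers 3 and 2 of 10 (7), with Hnf4a 3.57-fold higher and Amn and Cubn 6.22-fold and 3.24-fold lower. Bmp targets gave 3 and 1 of 10 (4), with Bmp4 higher at 48.4 ± 14.7 against 0.855 ± 1.48 CPM, Id2 9.19-fold higher and Bambi 7.79-fold lower. Retinoic acid targets gave 2 and 0 of 6 (3), with Cyp26a1 13.1-fold higher. Its reads in LPE (2.69 ± 4.67 CPM) lay in a single library, so the size of that fold is uncertain. Glycolysis and hypoxia genes gave 4 and 5 of 19 (9), Ndrg1 being higher at 70.4 ± 20.6 against 0.533 ± 0.923 CPM and the lactate transporter gene Slc16a3 6.98-fold lower. Glucocorticoid receptor targets gave 1 and 2 of 14 (6), with Glul 5.61-fold and Fkbp5 2.200-fold lower. The other counts were 1 and 1 of 8 (2) for mesenchymal genes, 1 and 0 of 6 (1) for Tgf-beta and Nodal targets, 0 and 2 of 7 (2) for interferon-stimulated genes and 1 and 2 of 19 (3) for amino acid and unfolded protein response genes. Camera's adjusted p over these 12 lists ran from 0.077 to 0.98.

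Of the 3 lists with fewer than 5 tested members, 4 of 20 pluripotency and epiblast markers were tested, and 2 rose in LPE against T (Tfcp2l1 and Klf4), while Pou5f1, Tfcp2l1 and Lin28a were lower in CPE than in LPE. In CPE against T, Pou5f1 and Lin28a fell 1.92-fold and 1.51-fold and Klf4 rose, a call lost without T replicate 1 or 3 or CPE replicate 1 or 2 (adjusted p = 0.129, 0.0872, 0.0885 and 0.0581). Of 20 trophoblast markers 4 were tested, and Gata2 and Elf5 rose in CPE against both other media, Gata2 to 79.00 ± 45.7 CPM from 0.426 ± 0.738 in LPE and 1.06 ± 0.117 in T. The call of Elf5 against T was lost without any of the T libraries or CPE replicate 1 or 2 (adjusted p = 0.132, 0.121, 0.145, 0.0521 and 0.0915). Of 14 fibroblast markers only Mfap5 was tested, at 231 ± 16.6 CPM in T, 117 ± 24.4 in LPE and 184 ± 30.02 in CPE. It was 1.98-fold lower in LPE than in T and was higher in CPE than in LPE, the latter call being lost without CPE replicate 1 or 2 (adjusted p = 0.0556 and 0.0567).

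By the fixed rule, the largest rises in CPE against LPE were those of Pgc (at least 79.1-fold higher), Stac2 (at least 70.3-fold), Nrp1 (at least 63.5-fold), Pon2 (at least 62.9-fold), the mucin-type glycoprotein gene Pdpn (at least 53.3-fold), Smpx (at least 49.99-fold) and Klk6 (at least 41.9-fold), which had 0 counts in LPE. The largest falls were Slc6a2 (at least 69.3-fold lower), Dpysl4 (at least 31.6-fold), the small heat shock protein gene Cryab (at least 21.7-fold), Gtsf1 (at least 19.2-fold), Kcnd3 (at least 18.5-fold), Pde9a (at least 16.8-fold) and Sspo (at least 16.6-fold), with 0 counts in CPE. Groups did not overlap for 31.3% of genes, against 10% by chance. Both media gave libraries of high noise between replicates, so the true folds of genes at 0 counts may lie below these bounds. LPE replicate 2 lay apart from the others on the principal component plot. Without that library 1758 genes were called.

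**Figure D3:**
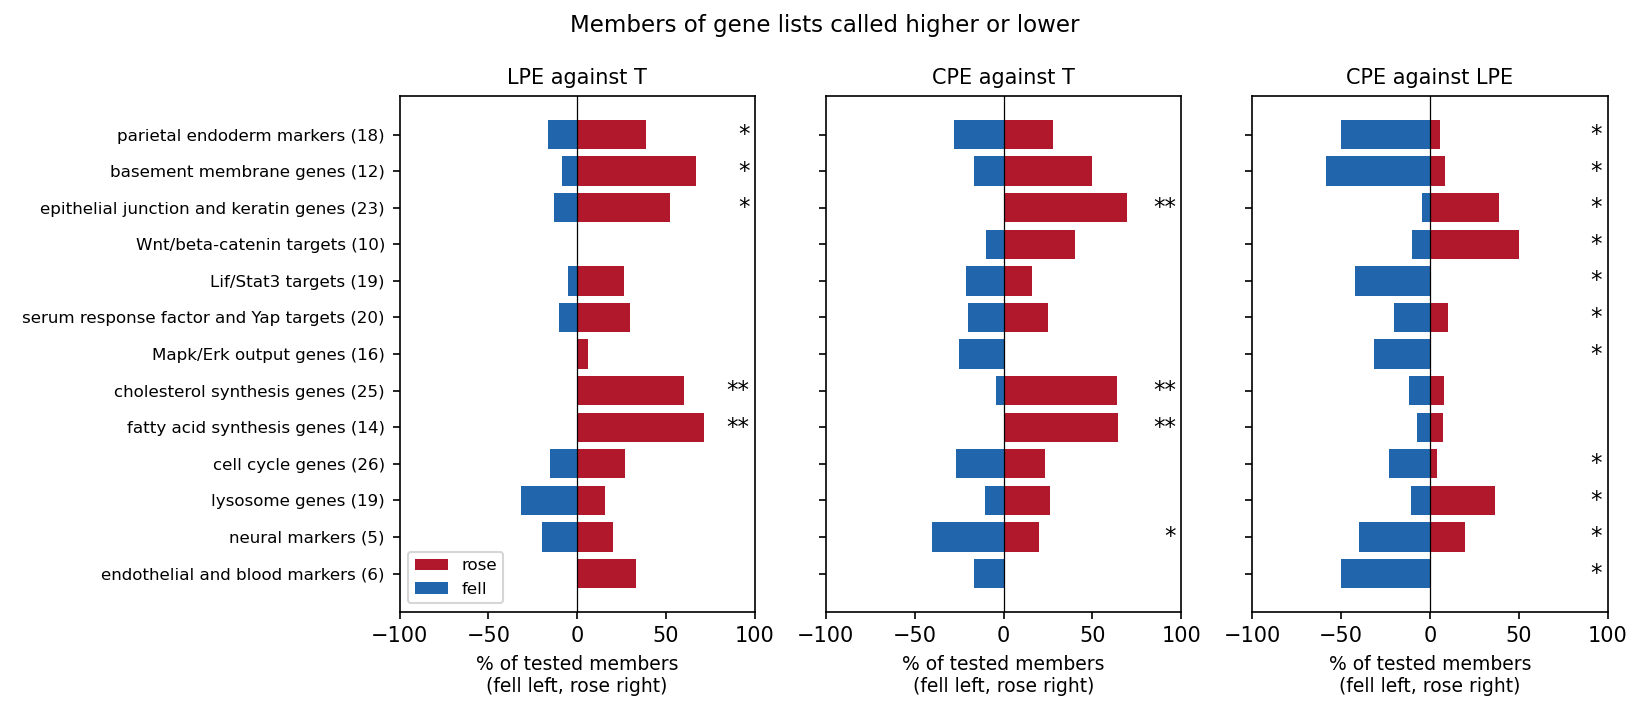
Share of the tested members of each list (number in parentheses) that rose or fell, in percent, for the 13 lists called in at least 1 comparison; 1 asterisk marks a camera adjusted p under 0.05 and 2 asterisks one that also holds with an estimated correlation. Cholesterol and fatty acid synthesis genes rose in LPE and CPE against T, with 15 and 16 of 25 and 10 and 9 of 14 members higher.

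**Figure D4:**
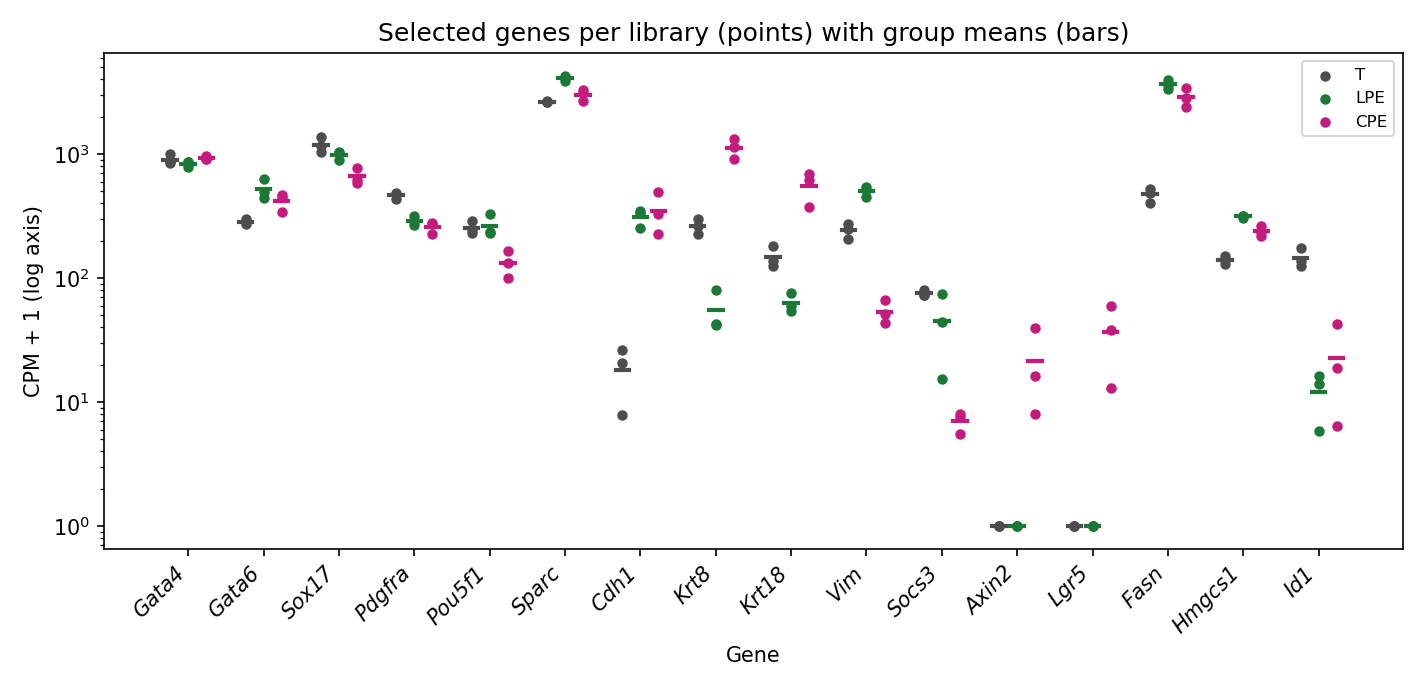
CPM + 1 on a log axis for 16 genes, with a point for each of the 9 libraries and a short bar at the mean of the 3 libraries of a medium. Cdh1 is higher in LPE and CPE than in T, Krt8 and Krt18 are lowest in LPE and highest in CPE, and Axin2 and Lgr5 are at 0 counts outside CPE.

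Over the 3 tests together, 705 genes were higher in T than in both other media and 901 lower, 285 were higher in LPE and 378 lower, and 427 were higher in CPE and 413 lower. The LPE and CPE changes against T overlapped, 901 genes being called higher in both and 705 lower in both, against 230 and 205 expected of independent lists. Both comparisons use the T libraries, so part of the excess may come from these, and 3 control libraries are too few to split. The fold changes had a correlation of 0.433 across genes, against 0.145 (0.118 to 0.179) in 20 simulations of unchanged groups against shared controls, and a covariance of 0.699 against 0.0527 (0.0388 to 0.0688). LPE and CPE also both differ from T in genes detected and in replicate noise (above). The simulations hold no shift in means from such a library difference, so they cannot tell it from a response to the media. Fasn, Cdh1 and Ctsb were among the genes higher in both, and Id1 and Pdgfra among those lower in both. A further 84 genes were called in opposite directions against T, 35 higher in LPE and 49 higher in CPE. For all 84 the difference between CPE and LPE was itself called, which was to be foreseen, since opposite changes from the same T libraries add up. Krt8 and Krt18 were higher in CPE and lower in LPE, and Vim the reverse.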

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

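For 18 of the named genes, LPE and CPE were called in opposite directions against T. The test of CPE against LPE called all 18. This was to be foreseen, since opposite changes from the same T libraries add up in that test, so it is no separate support. Among genes higher in CPE than in LPE, the log2 fold changes between the media were 4.38 for Krt8, 3.16 for Krt18, 2.30 for Ctsd, 1.27 for Rhox5 and 5.04 for Col18a1, and 9.85, 10.20 and 10.44 for Klk6, Pdpn and Pon2, whose values are fitted and no bounds because LPE had 0 counts. Among genes lower in CPE they were -3.25 for Vim, -2.49 for Glul, -1.70 for Cubn, -0.91 for Hspa5, -1.90 for Rrm2, -2.80 for Slc16a3 and -3.77 for Tubb3. For Slc6a2 (-10.41), Dpysl4 (-9.27) and Cryab (-8.74), CPE had 0 counts and the values are again fitted. Some of the calls against T that make up these opposite directions were weak. Col18a1 in CPE against T lost its call without any of the T or CPE libraries (adjusted p = 0.0565 to 0.135), and Tubb3 in LPE against T without T replicate 1 or 2 or LPE replicate 2 (adjusted p = 0.0562, 0.0728 and 0.0584). Rhox5 in CPE against T had an adjusted p of 0.046 and Cryab in LPE against T one of 0.04.

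On the other strand, which the comparisons did not use, 84 genes had more reads than on their own strand in all 9 libraries, with over 3 counts there. Over all libraries the highest were Serhl2 with 4500 reads against 153, Srr with 3926 against 440 and Map3k12 with 3453 against 238. Where these reads come from was not tested.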

How the results depend on the processing

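Of 6049 values for 268 named gene results over 23 settings, 5739 kept their direction and side of the threshold, 293 lost the call, 12 gained one and 5 reversed. The 5 were not called with all libraries: Pou5f1 in LPE against T (-0.0062 without T replicate 1, -0.11 without LPE replicate 2, up to 0.158 without T replicate 3), Fkbp5 in LPE against T (-0.0058 without T replicate 1, 0.23 without T replicate 3), Gata4 in CPE against T (-0.0065 without T replicate 1, 0.115 without T replicate 2) and Cdh1 in CPE against LPE (-0.178 without CPE replicate 1, 0.388 without CPE replicate 3). The cause was not tested.

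Counts are given for LPE against T, CPE against T and CPE against LPE in that order. An adjusted p under 0.01 left 1698, 1870 and 899 genes called, 738 genes higher in a single medium (1417 at 0.05) and 943 shared by both comparisons with T (1606 at 0.05), and a test against a 1.5-fold change left 982, 1248 and 520, as the stricter thresholds require. DESeq2 called 2833, 3075 and 1948 genes. Fits of only the 6 libraries compared called 2695, 3664 and 1103. Leaving out each library gave 1896 to 2853, 2083 to 3490 and 1298 to 1758 genes, 957 to 1493 higher in a single medium and 1091 to 1708 shared. The lists called then ran from 5 to 6, from 4 to 5 and from 10 to 14. Camera with an estimated correlation called 2 lists in LPE against T and 0 in CPE against LPE, where the count had been 5 and 11. Fry, which compares a list with no other genes, called 14 in LPE against T and 9 in CPE against T. Other normalizations and filters moved no count by over 1.5 times. Of the alternatives chosen after seeing the data, only list tests on the 6 libraries compared did, with 8 lists called in LPE against T, the cause of which was not tested. Weights per group in limma voom called 2952, 3907 and 1118 genes, and division by replicate noise 3123, 4102 and 1503.

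Equal replicate numbers did not pair the libraries, since deviations of same-numbered libraries from their group means correlated at -0.0266 to 0.0118. With the replicate number as a block, 2558, 2751 and 1500 genes and 5, 4 and 11 lists were called, 1326 genes were higher in a single medium and 1517 were shared. In the simulations 2-fold changes were found in 37% to 45% of cases.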

Other observations

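The genes of this paragraph and the next were chosen after their values were seen. Among the changes not described above, Dnmt3l, the cofactor of de novo DNA methylation, was 6.74-fold higher in LPE than in T (909 ± 69.02 against 135 ± 29.98 CPM), whereas the methyltransferase gene Dnmt3a was 6.84-fold lower in CPE (10.1 ± 4.61 CPM) than in LPE (69.3 ± 22.97 CPM). Fgf10 stood at 83.5 ± 1.99 CPM in T, 135 ± 25.9 in LPE and 1.25 ± 1.08 in CPE. Bex1, Akr1c14 and Igf1 were 141-fold, 9.98-fold and 16.1-fold higher in CPE than in LPE. Krt4, a keratin of stratified epithelia, rose in both serum-free media, from 12.8 ± 5.44 CPM in T to 205 ± 17.4 in LPE and 201 ± 72.1 in CPE, so it did not share the opposite directions of Krt8 and Krt18. The cell cycle inhibitor gene Cdkn1c, which is imprinted, was 7.78-fold lower in LPE and 7.56-fold lower in CPE than in T.

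The imprinted genes H19, Igf2 and Igf2r were higher in CPE than in LPE and T. H19 had 56.6 ± 4.89 CPM in T, 5.46 ± 4.797 in LPE and 844 ± 410.2 in CPE, Igf2 had 2.24 ± 0.528, 2.34 ± 4.06 and 347 ± 176, and Igf2r had 14.01 ± 4.801, 27.7 ± 9.66 and 523 ± 140.4. Peg3 was 4.84-fold lower in LPE than in T and 5.25-fold higher in CPE than in LPE.

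All tests of this pattern were chosen after its values were seen. A single odd CPE library is argued against, since for H19 and Igf2 the lowest CPE library was above the highest LPE or T library, by 7.21 times for the one with the smaller ratio. Fibroblasts in the CPE cultures are argued against by 0 CPM for the sum of Col1a1, Col1a2, Col3a1, Dcn and Lum in the highest CPE library. Trophoblast cells stay open, as Prl3d1, Prl3b1, Tpbpa and Psg29 summed to 2.27 CPM in the highest CPE library, though LPE libraries reached 1.92 and Gata2 and Elf5 also rose. A joint change of imprinted genes stays open: in a list without the 7 members already seen, 7 of 17 rose and 0 fell in CPE against LPE. This did not pass (limma camera adjusted p = 0.056, 0.0204 before adjustment). The adjustment was over 11 lists, which were the nested imprinted lists and the protein families below. In LPE against T 2 rose and 7 fell (camera adjusted p = 0.036, and 0.096 as the adjusted p with an estimated correlation), and in CPE against T 3 rose and 3 fell (adjusted p = 0.88). The list without only H19, Igf2 and Igf2r, at 0.00201 before adjustment, is void because it holds 4 members already seen.

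The smaller number of genes in LPE and CPE than in T was tested after it was seen, except for the last test. Lower depth is argued against by the reads themselves, since every T library had fewer assigned reads than every LPE or CPE library. Thinning to equal reads could hardly narrow the gap, so it adds little. After it the lowest T library detected 392 genes more than the highest LPE or CPE library. Duplicated reads from fewer molecules may account for it: the lowest LPE or CPE replicate pair had 3.60 times the noise of the highest T pair at 20 to 99 counts. Variation between cultures would make the excess noise grow with the count, but from genes of 20 to 99 counts to a bounded band of higher counts, starting at 200, it grew at most 1.29-fold. Genes switched off in the serum-free media stay open, since of genes found in every T library and missing from at least 1 library of a medium, 20.6% in CPE and 22.7% in LPE were missing from all 3. Most of these had few reads in T as well. The median T count was 3.67 for the 231 genes missing from CPE and 3 for the 345 missing from LPE. Only 5 and 13 of them averaged at least 20 counts in T, so many may have been missed at low count. The medium and the library quality cannot be told apart in this design.

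Families of mostly small proteins had lower medians in LPE and CPE, in a test written before the values were seen. The highest of 10 medians over 5 families and both comparisons with T was -0.28, in histone genes in CPE. All 5 were below 0 under TMM, relative log expression, upper-quartile and library-size scaling. These families, and the large-protein families below, were picked by gene symbol and not by size, so single members may differ in size. Both comparisons share the T libraries. In LPE 4 rose and 50 fell of 76 ribosomal protein genes (median -0.51), 3 and 26 of 66 mitochondrial ribosomal protein genes (-0.59), 1 and 11 of 32 complex I genes (-0.44), 4 and 16 of 35 proteasome genes (-0.39) and 2 and 9 of 23 histone genes (-0.49), and in CPE 6 and 47 (-0.55), 2 and 19 (-0.45), 1 and 8 (-0.35), 3 and 18 (-0.49) and 2 and 5. Camera of limma called all 5 downward in LPE (adjusted p from 2.2e-11 to 0.0057 over 11 lists) and all but histone genes in CPE (1.1e-10 to 0.039, histone genes 0.21), whereas with an estimated correlation the adjusted p was 0.0714 to 0.318 and 0.198 to 0.678, so none passed. Of large-protein families in LPE, laminin (5 rose and 0 fell of 7, adjusted p = 1.5e-05) and myosin and actinin genes (10 and 1 of 22, 0.0025) were called upward and collagen genes (2 and 2 of 6, 0.19) were not, none passed with an estimated correlation (0.0714 to 0.252), and in CPE none was called (4 and 2, 7 and 2, and 2 and 1, at 0.19 to 0.51). Loss of short transcripts in library preparation may contribute, but transcript length was not analysed here. A change of expression of these families with the medium remains open and untested. Rn5s, whose 5S ribosomal RNA is short, was higher instead. It had 5.98 ± 6.82 CPM in T, 192 ± 39.5 in LPE and 180 ± 11.9 in CPE. A single gene with close copies does not settle this, and ribosomal RNA was removed before sequencing. Reads mapping to several places, which enter no gene, made up 64.9% to 67.6% in T and 51.7% to 59.9% in LPE and CPE. Members of these families with close copies are therefore uncertain.

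Other splits of the 6 libraries of a comparison into 3 and 3 were counted, as planned before the values were seen. There are 10, the real split included, so a share under 0.05 cannot be reached. The real splits called 2716, 2928 and 1624 genes in LPE against T, CPE against T and CPE against LPE, and only 1 of 10 splits reached that number in each, the highest other split calling 0 by edgeR. At an unadjusted p under 0.05 the other splits had 103 to 211, 40 to 111 and 360 to 486 genes. Each other split holds libraries of both media on each side, so the difference between the media enters the spread. Few calls there were therefore to be foreseen, and no conclusion is drawn from them.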
